A study of Mus musculus with 6 samples.

How the data were processed

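RNA was measured in sorted splenic germinal centre B cells of 6 samples, 3 labelled Cg1-cre control and 3 labelled as carrying DAF-TM as well. Per the labels' protocols, 10 ng of total RNA per sample were reverse transcribed with an oligo-dT primer (SMART-Seq v4), and 12 indexed libraries shared 1 lane of single-end sequencing with 100 nt reads and at least 30M of them per sample. Samples other than these 6 were not analysed here. Per the submitters' processing notes, bcl2fastq, HISAT2 and featureCounts were used, without versions, and the file header names the genome build mm10. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so counts of paralogs and of overlapping or antisense genes are uncertain. An oligo-dT kit of this kind amplifies without molecular identifiers, so floors cover counting error only. The intervals printed for medians and ratios were drawn by resampling genes, not libraries, so they do not cover the spread between libraries.

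The authors deposited raw counts per gene symbol, whole numbers in 23412 rows, with no normalization. Every column was mapped to a sample by its name. DAF-TM replicates 2 and 3 held the same count in every row and were used as 1 library, so 5 libraries entered the fits in place of the planned 6. The totals ran from 7257339 to 12783965 counts. In 27 rows the symbol had been turned into a date by a spreadsheet, which made 25 different names, and these rows held at most 0.266% of a library's counts. They were left in the library sizes and are not named. The table held 0 rows for immunoglobulin or T cell receptor segments or constant regions and 0 for mitochondrially encoded genes, so the planned list of antibody heavy chain genes had no values. Names and positions came from a RefSeq table of assembly GRCm38.p6, the same build, to which 23226 of the names were matched. Of 998 entries in the gene lists 981 were matched to a row, 14 through older symbols.

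Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM factors, filterByExpr by group, glmQLFit with robust estimation and a two-sided glmQLFTest with Benjamini-Hochberg adjustment over 18767 genes and a threshold of 0.05. All adjusted p-values of single genes come from this test unless another tool is named. The biological coefficient of variation was 0.177 and the fit had 3 residual degrees of freedom. Values per library are TMM-normalised CPM, counts scaled to the library size, given as mean ± SD with n = 3 control and 2 DAF-TM libraries unless SE is named. Sex-linked and receptor totals are unadjusted CPM, and per-library differences used a pseudocount of 0.5. A count of 0 was given an upper limit of 3 counts. Data were simulated from the means, library sizes and trended dispersion of these libraries. They held 18767 genes in 2 against 3 libraries, with 50 genes changed per fold size. The procedure recovered 10% of genes changed 1.5-fold, 38% at 2-fold, 76% at 4-fold and 90% at 8-fold. Of its 109 calls 2 were false. The simulated genes varied independently, without dispersions of their own, mixed sexes or the trend with expression level described below. That share of false calls therefore does not carry over to the real data.

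The gene lists were written down before the data were examined, as were the tests, the rule for naming genes and all alternatives except those named as added. Lists with at least 5 tested members entered camera with the preset correlation of 0.01, Benjamini-Hochberg adjusted over 31 lists, and 23 passed. With an estimated correlation 0 of these calls held, and fry, which tests whether a list's genes move on balance one way, called 1, complement (adjusted p = 0.0172), a call lost without Cd55 (0.141). Medians were compared with 10000 random lists drawn from 50 bins of expression level. Genes were drawn singly, so the percentiles take no account of list members that vary together. Named genes were Cd55, then the largest changes (12 up, and all 6 that qualified down) among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out sex-linked genes and predicted or unnamed models. To these were added the 3 members of lowest p in the 8 lists of lowest p and a fixed set of complement and germinal centre genes. Chance gives no overlap in 20% of genes with groups of 3 and 2, and 3808 of the 18767 genes tested showed no overlap. Further called members of the lists, and the genes outside the rule, were named after their values were seen. The values of some single genes are not reported here. Numbers shared by replicates of both groups do not pair the libraries: the labels name no shared litter or day, and the deviations of 2 DAF-TM libraries mirror each other. No correction for sex was made in the main fit.

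The alternatives were RLE and upper-quartile factors, no low-count filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a threshold of 0.1, glmTreat against a 1.2-fold change, estimated correlations and fry. Fits that leave out a DAF-TM library keep 1 in that group, which is assumed to vary like the controls. Added after the data were seen were all 6 columns as deposited, Xist level as a covariate, Cd55 left out of the lists (with the preset and with estimated correlations, and with fry), a loess correction for expression level, and the natural killer and plasmacytoid dendritic cell lists. Figures and resampling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.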

Results

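Splenic germinal centre B cells were profiled by RNA sequencing in mice that carried the Cg1-cre allele, which drives Cre recombinase in B cells of the germinal centre. Control mice carried this allele alone, and DAF-TM mice also carried 2 copies of a Cre-dependent DAF-TM cassette at the Rosa26 locus. DAF, decay accelerating factor, is a membrane protein that limits complement activation at the cell surface, and its mouse gene is Cd55. Cells positive for B220, GL7 and Fas (CD95) were collected on day 10 after immunization with sheep red blood cells. Each group had 3 replicates in the labels. The columns of DAF-TM replicates 2 and 3 were identical in all 23412 rows, so they differed by less than the sampling noise and were counted as 1 sample, called DAF-TM library 2 below. Every other pair of columns differed in at least 21585 rows. The comparison therefore rested on 3 control and 2 DAF-TM libraries, with total counts of 9627306, 12783965 and 7257339 in control libraries 1 to 3 and of 11280400 and 10684753 in DAF-TM libraries 1 and 2. The labels do not say whether a library came from 1 mouse or from pooled mice, so p-values refer to libraries, not mice. The fit drew the spread of each gene strongly to that of other genes (median prior degrees of freedom 1153, against 3 residual ones). For most genes the p-value therefore rests mainly on the spread pooled over genes.

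The sex-linked genes differed between libraries of 1 group. Xist, the RNA of the inactive X chromosome of females, stood at 744 CPM in control library 1 and at 2.42 and 2.89 in control libraries 2 and 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0.104, 653 and 483 CPM in the same libraries. DAF-TM library 1 held both Xist, at 291, and Y-linked reads, at 284, whereas DAF-TM library 2 held Xist at 797 and had 0 Y-linked counts, which allows up to 0.281 CPM for counting error only. Olfactory and vomeronasal receptor genes, which B cells are not known to use, took 1174 CPM in DAF-TM library 2, 585 in DAF-TM library 1 and 649 to 832 in the controls.

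**Figure D1:**
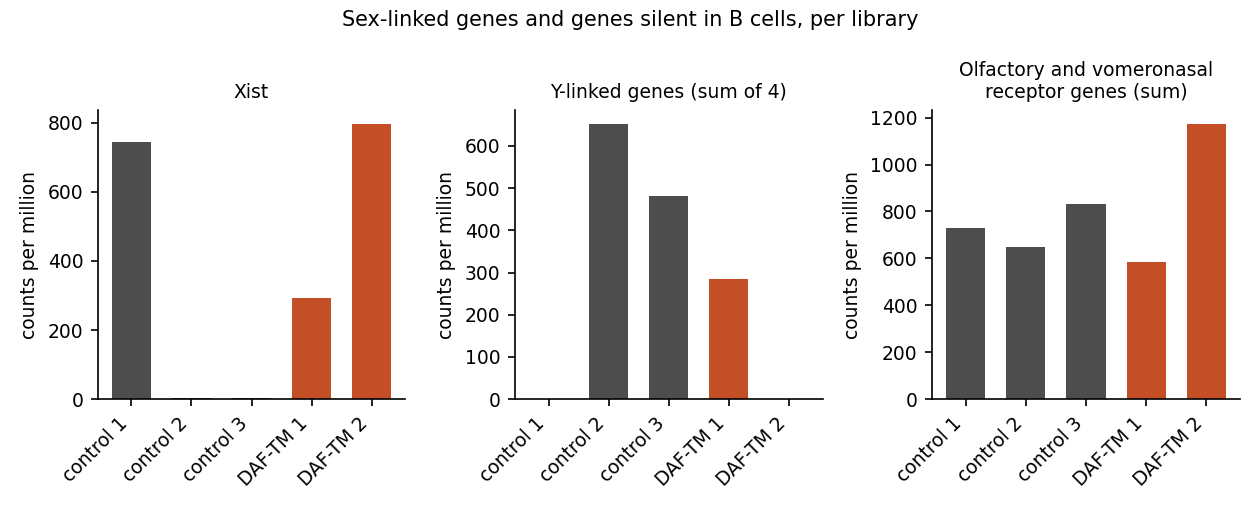
Bars give the unadjusted CPM (linear axis from 0) of Xist, of 4 Y-linked genes and of the olfactory and vomeronasal receptor genes in control libraries 1 to 3 (grey) and DAF-TM libraries 1 and 2 (orange). DAF-TM library 1 shows both Xist (291) and Y-linked reads (284), and DAF-TM library 2 has the highest receptor total (1174).

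Cd55, on chromosome 1 (130429798 to 130465009, GRCm38), was the gene with the strongest rise. It stood at 28.9 ± 5.47 normalised CPM in control cells (SD, n = 3) and at 720 ± 8.93 in DAF-TM cells (SD, n = 2), a 24.8-fold rise (log2 fold change 4.63, SE 0.18, edgeR adjusted p = 1.99e-110). The raw counts were 271, 405 and 172 in the controls and 7911 and 8585 in the DAF-TM libraries. Cd55b, a neighbouring paralog listed as Daf2, stayed near the floor, at 1.12 ± 0.64 and 1.34 ± 0.74 CPM, and the counting does not show how reads shared by the pair were assigned. The labels do not give the sequence of the cassette, so the counts do not separate its transcripts from those of the endogenous gene.

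Of 24 complement genes tested, Cd55 alone rose and none fell over all genes tested, and adjusted over the list alone 2 rose, Cd55 and Itgam. The median log2 fold change was 0.30, and the list passed the set test (camera adjusted p = 8.74e-08; adjusted p = 0.154 with an estimated correlation). Without Cd55 the median of the other 23 was still 0.30, and the mean was 0.32 in place of 0.50 (camera adjusted p = 0.00562; adjusted p = 0.299 with an estimated correlation). Random lists matched in level to all 24 genes had a median of 0.12 (complement at percentile 98.4). In DAF-TM library 2 the complement median was 0.30 against 0.23 (percentile 77.0), and in library 1 0.22 against 0.00 (percentile 99.65). Itgam and Itgax, chains of the complement receptors that bind fragments of C3, had log2 values of 0.87 (adjusted p = 0.0676) and 0.74 (adjusted p = 0.846). Itgax is also in the dendritic cell list. Markers of dendritic cells (median 0.55), macrophages (0.53) and natural killer cells (0.92 over members not seen before) also had positive medians. The receptors for the C3a and C5a fragments did not pass, C3ar1 at 0.16 ± 0.31 (SE) and C5ar1 at 0.61 ± 0.35. Nor did the remaining regulators and receptors named beforehand pass: Cr2 stood at -0.19 ± 0.17, Cr1l at -0.26 ± 0.17, Cd46 at -0.12 ± 0.45 and C3 itself at 0.45 ± 0.32. Without DAF-TM library 2, C3ar1 stood at -0.02 and Cr2 at 0.12. Cd46 stood at 0.02 without DAF-TM library 1 and at 0.03 without control library 1. Itgam stood at 0.45 and Itgax at 0.28 without DAF-TM library 1, and at 1.19 and 1.09 without library 2. C3 ran from 0.24 without control library 2 to 0.87 without control library 3.

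Among 18767 genes tested, 77 changed, 70 higher and 7 lower, at an edgeR adjusted p under 0.05, and 1078 had an unadjusted p under 0.05. The 12 largest rises under the naming rule included Klrd1, Vcam1, Ccl5, Ctse, Gzma, Klra9, Slc40a1, Ccr7, S100a10, S100a6 and Prkcq, between 4.86-fold for Klrd1 and 3.32-fold for Prkcq. Without DAF-TM library 1 the log2 fold change of Klrd1 was 1.17 in place of 2.28, so its place as the largest rests on that library. Ctse, which encodes the aspartic protease cathepsin E, was the most abundant of these: it rose from 32.5 ± 10.3 to 130 ± 32.8 CPM (SD, n = 3 and 2; log2 fold change 1.99, SE 0.17, adjusted p = 1.55e-22). The calcium-binding S100a10 rose 3.43-fold and S100a6 rose 3.42-fold, and their log2 values of 1.78 and 1.77 were 1.15 each without DAF-TM library 1. BC094916, a gene outside the naming rule and singled out after its values were seen, rose 11.9-fold, from 0.985 ± 0.498 to 12.4 ± 2.35 CPM.

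**Figure D2:**
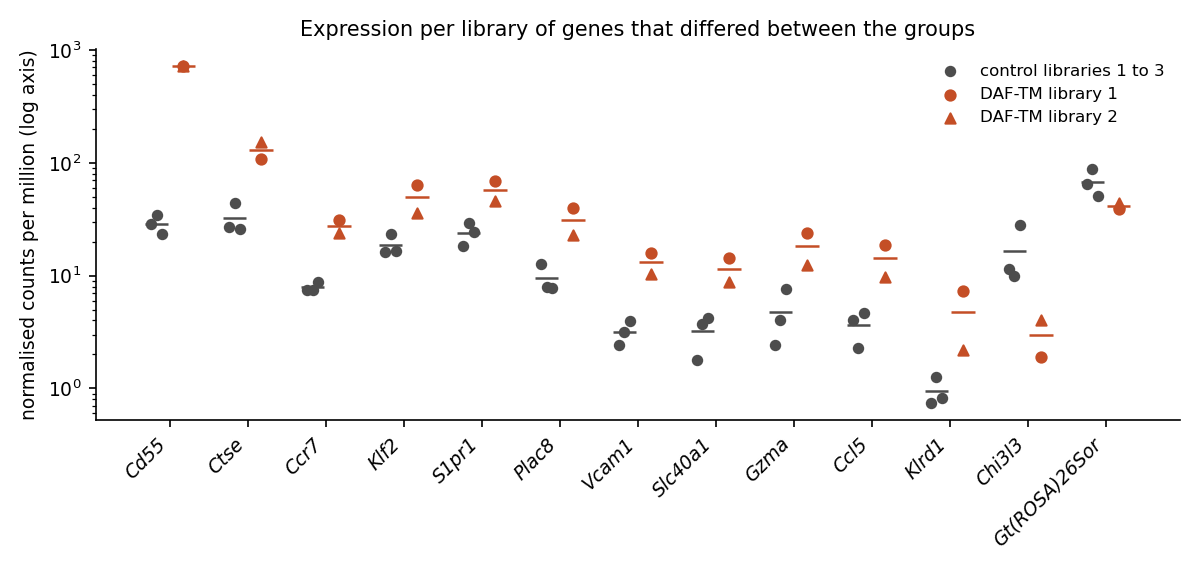
Points give TMM-normalised CPM (log axis) of 13 genes in control libraries 1 to 3 (grey) and in DAF-TM library 1 (circle) and 2 (triangle), and short lines the group means. Cd55 has the widest gap (28.9 against 720), and DAF-TM library 1 lies above library 2 in most of the genes that rose.

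The number of calls depended on single libraries and on the tool. Without DAF-TM library 1, the one with both Xist and Y-linked reads, 14 genes were called, and 9 of the 77 were kept. It was 43 without control library 1, 44 without control library 3 and 118 without DAF-TM library 2. Without control library 2, 79 genes were called, 55 of them among the 77. DESeq2 called 32 genes and limma-voom 49, all of them among the 77. Cd55, Ctse, Ccr7, Cnn3, BC094916 and G530011O06Rik were among the 7 genes called in all 5 fits that left out 1 library. Of the other large rises, Vcam1 (adjusted p = 0.0652), Ccl5 (0.272), Gzma (0.288) and Slc40a1 (0.352) were lost without DAF-TM library 1 and in no other fit that left out 1 library. Gzma (0.505) and S100a10 (0.322) were also lost with DESeq2, which gave no adjusted p for Klrd1 and Klra9. Klrd1 (0.561), Klra9 (0.452), S100a10 (0.272), S100a6 (0.518) and Prkcq (0.176) were lost without it too, and each also without at least 1 control: Klrd1 (0.0629), Klra9 (0.135), S100a6 (0.0727) and Prkcq (0.0961) without control library 1, S100a10 (0.478), S100a6 (0.0761) and Klrd1 (0.0594) without control library 3, and Klra9 (0.479) and Prkcq (0.09) without control library 2. The log2 fold changes of Prkcq and Klra9 without DAF-TM library 1, 1.70 and 1.74, were close to those with all libraries, 1.73 and 1.91, while those of Ccl5 and Gzma were 1.44 and 1.43 in place of 1.995 and 1.98.

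Some genes that guide lymphocytes through lymphoid organs rose in the DAF-TM libraries. Of 20 FOXO1 targets and egress genes, 4 rose, none fell and 16 did not pass (5 rose adjusted over the list alone; median log2 fold change 0.25; camera adjusted p = 2.44e-10; adjusted p = 0.203 with an estimated correlation). The 4 included Ccr7, the chemokine receptor for the T cell zone, from 7.91 ± 0.713 to 27.3 ± 5.06 CPM (adjusted p = 1.47e-11), Klf2, a transcription factor of quiescent lymphocytes, from 18.8 ± 4.14 to 49.5 ± 19.5 (4.41e-10), and S1pr1, the receptor that guides exit from lymphoid tissue, 2.37-fold (8.51e-09). Foxo1 itself had a log2 value of 0.11 ± 0.17 (SE). Without DAF-TM library 1, Klf2 (log2 fold change 0.91, adjusted p = 0.246) and S1pr1 (0.91, 0.195) were not called. T cell markers (median 0.72) and natural killer cell markers (median 0.92 over members not seen before) also had positive medians in these libraries. Il7r belongs to both the egress and the T cell list.

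The same 4 genes and Cd55 were the 5 of 17 naive or follicular B cell genes that rose (5 adjusted over the list alone), and none fell. That list had a median of 0.02, which stood at -0.00 with RLE size factors, and a mean of 0.60 (camera adjusted p = 3.22e-14; adjusted p = 0.203 with an estimated correlation). Without Cd55 the median was 0.01 and the mean 0.35 (camera adjusted p = 5.23e-06; adjusted p = 0.334 with an estimated correlation). Other members were level: Fcer2a, the IgE receptor CD23, stood at 221 ± 60 and 220 ± 13 CPM, and Faim3, the IgM receptor, at 286 ± 9.1 and 308 ± 21. Among 16 memory B cell genes, Hhex (1.95-fold) and the integrin chain Itgb7 (2.17-fold) rose and none fell (3 rose adjusted over the list alone; median 0.17; camera adjusted p = 0.000497; adjusted p = 0.466 with an estimated correlation), and without DAF-TM library 1 the direction turned (adjusted p = 0.239). Of 18 marginal zone and B1 cell genes Plac8 rose 3.29-fold and none fell (4 rose adjusted over the list alone; median 0.32; camera adjusted p = 1.23e-05; adjusted p = 0.334 with an estimated correlation), and this list also turned without DAF-TM library 1 (adjusted p = 0.843). Of 29 plasma cell genes Prdm1, the regulator of plasma cell fate, rose 1.75-fold and none fell, the same count as adjusted over the list alone, and the list did not pass (median 0.10, from 0.31 in DAF-TM library 1 and -0.24 in library 2; camera adjusted p = 0.372). Hhex (0.59), Itgb7 (0.518), Plac8 (0.0652) and Prdm1 (0.595) lost their calls without DAF-TM library 1, where their log2 values were 0.46, 0.59, 1.28 and 0.38 in place of 0.96, 1.11, 1.72 and 0.81. Hhex (0.302 and 0.415) and Prdm1 (0.327 and 0.0761) also lost them without control libraries 1 and 3.

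A minority of the markers of cells that the sort was meant to remove rose. Of 23 T cell genes 2 rose and none fell, the transcription factor Tcf7 (2.58-fold, adjusted p = 0.013) and the receptor chain Cd3d (2.87-fold, adjusted p = 0.0293), while Il7r, at a log2 value of 1.22, did not pass (adjusted p = 0.102). Adjusted over the list alone 9 rose, and the list median was 0.72 (camera adjusted p = 5.02e-11; adjusted p = 0.154 with an estimated correlation). Of 25 macrophage genes 5 rose (6 adjusted over the list alone) and none fell: the adhesion molecule Vcam1 (4.16-fold), the iron exporter Slc40a1 (3.53-fold), the growth factor receptor Csf1r (2.18-fold), the complement component C1qb (3.02-fold) and transferrin, Trf (2.39-fold). The median was 0.53 (camera adjusted p = 8e-10; adjusted p = 0.203 with an estimated correlation). Apoe, an abundant macrophage transcript, stood at 694 ± 35 and 693 ± 120 CPM. Summed over each list, macrophage genes took 1466 ± 130 and 1488 ± 390 CPM and T cell genes 454 ± 3.36 and 455 ± 4.32. Dendritic cell genes took 280 ± 22.5 and 290 ± 21.1. In the controls 5 of the 25 macrophage, 3 of the 23 T cell and 2 of the 15 dendritic cell genes reached 10 CPM. The sums therefore follow a few abundant members and would hide a small share of such cells. Random lists of matched level had medians of 0.18 for T cell, 0.14 for macrophage and 0.17 for dendritic cell genes. In DAF-TM library 2 these lists stood at 0.70, 0.46 and 0.37, against 0.32, 0.27 and 0.31 for random lists (percentiles 100, 97.4 and 70.0). Among 15 dendritic cell genes Siglech rose 3.22-fold and none fell (2 rose adjusted over the list alone; median 0.55; camera adjusted p = 2.55e-05; adjusted p = 0.334 with an estimated correlation). Without DAF-TM library 1, the calls of Tcf7 (0.352), Cd3d (0.246), Vcam1 (0.0652), Slc40a1 (0.352), Csf1r (0.548), C1qb (0.558), Trf (0.402) and Siglech (0.246) were lost. The log2 fold changes in that fit were close to those with all libraries for Tcf7 (1.33 and 1.37), Cd3d (1.63 and 1.52), Trf (1.18 and 1.25) and Siglech (1.497 and 1.689), and smaller for Vcam1 (1.70 and 2.06), Slc40a1 (1.42 and 1.82), Csf1r (0.65 and 1.12) and C1qb (0.98 and 1.59). Cd3d was lost in every fit that left out 1 library (0.114 to 0.391), C1qb without any control (0.143 to 0.45), Tcf7 without control libraries 1 (0.113) and 2 (0.237), Csf1r without control library 3 (0.385), Siglech without control library 1 (0.055), and Trf without control libraries 1 (0.224) and 3 (0.13) and DAF-TM library 2 (0.053).

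Natural killer cell receptors and granule genes were among the genes called higher, and a list of 22 such markers was added after the data were examined. Of its members 7 were put in after their values had been seen, Klrd1, Klrk1, Klrb1c, Ncr1, Gzma, Nkg7 and Ccl5, and they are not independent evidence. Of the 15 members whose values had not been seen, Il2rb and Ctsw rose, none fell and 13 did not pass, all 15 with positive log2 values (8 rose adjusted over the list alone; median 0.92). Gzma, a protease of cytotoxic granules, rose from 4.72 ± 2.66 to 18.3 ± 8.11 CPM (adjusted p = 1.72e-07), and the chemokine Ccl5 from 3.65 ± 1.22 to 14.3 ± 6.39 (4.12e-07). The 22 genes summed to 71.6, 71.8 and 93.6 CPM in control libraries 1 to 3 and to 213 and 141 in DAF-TM libraries 1 and 2. Klra9 belongs to a family of near-identical killer cell lectin genes, so its single value is uncertain. The 9 called members lost their calls without DAF-TM library 1, at adjusted p from 0.272 for Nkg7 to 0.574 for Il2rb and log2 fold changes from 0.43 for Il2rb to 1.44 for Ccl5. Klrd1 (0.0629), Klrk1 (0.125), Klrb1c (0.323), Ncr1 (0.265) and Il2rb (0.283) were also lost without control library 1, Ncr1 (0.123) and Ctsw (0.413) without control library 2, and Klrd1 (0.0594), Ncr1 (0.0529), Il2rb (0.128) and Ctsw (0.182) without control library 3.

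Of 16 neutrophil genes 1 fell and 15 did not pass. Chi3l3, a secreted chitinase-like protein now named Chil3, fell from 16.5 ± 10.1 to 2.98 ± 1.53 CPM (log2 fold change -2.44, SE 0.40, adjusted p = 0.000924). Adjusted over the list alone 2 fell and 2 rose (median -0.73; camera adjusted p = 0.00408; adjusted p = 0.548 with an estimated correlation). The call of Chi3l3 was lost without DAF-TM library 1 (adjusted p = 0.537) and without library 2 (0.565), and its log2 value ran from -1.81 without control library 3 to -3.09 without DAF-TM library 2. The list turned without DAF-TM library 1 (adjusted p = 0.568). Other abundant members of the list varied widely among the controls, with S100a8 at 37.3 ± 27 and 10.8 ± 8.8. Erythroid genes (19, median 0.05, camera adjusted p = 0.828), platelet genes (12, median 0.21, 0.201) and follicular dendritic and stromal genes (16, median 0.23, 0.476) did not pass, and no member of these rose or fell, nor did any adjusted over the list alone.

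Interferon-stimulated genes were higher as a list. Of 43 genes 2 rose and none fell, Ifi203 (2.12-fold, adjusted p = 0.000179) and the RNA sensor Ddx58 (1.79-fold, adjusted p = 0.00295), and 35 had positive values. Adjusted over the list alone 7 rose (median 0.38; camera adjusted p = 4.52e-10; adjusted p = 0.286 with an estimated correlation). Irf9, a subunit of the interferon-activated transcription factor, had a log2 value of 0.58 and did not pass (adjusted p = 0.104). Its value was 0.31 without DAF-TM library 1 and 0.80 without DAF-TM library 2. Without DAF-TM library 1 the list no longer passed (adjusted p = 0.0647), and both genes lost their calls (adjusted p = 0.272 for Ifi203 and 0.539 for Ddx58; log2 0.95 and 0.48 in place of 1.08 and 0.84). Ddx58 was also lost without control library 1 (0.074). Ifi203 belongs to a family of similar neighbouring genes. Markers of T cells (median 0.72), macrophages (0.53), dendritic cells (0.55) and natural killer cells (0.92 over members not seen before) also had positive medians. The mean summed CPM of the T cell, macrophage and dendritic lists was close to that of the controls, but few members of these lists are abundant. The 15 natural killer genes not seen before summed to 56.7 ± 6.30 CPM in the control and 99.7 ± 20.5 in the DAF-TM libraries.

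No transcript of the list that defines germinal centre B cells was called. All 28 identity genes were tested, 1 of them had a positive log2 value, and the median was -0.15 (camera adjusted p = 8.25e-06; adjusted p = 0.334 with an estimated correlation). Bcl6, the master regulator of the germinal centre, stood at 293 ± 18 and 226 ± 17.5 CPM, 0.773 of the control level (log2 -0.37, adjusted p = 0.795). Its values did not overlap between the groups, which was also true of 3808 of the 18767 genes tested, near the 20% that chance gives. Changes of this size would mostly go uncalled, since 10% of simulated 1.5-fold changes were recovered. Of 19 dark zone genes none was called (median -0.12; camera adjusted p = 0.00197; adjusted p = 0.209 with an estimated correlation), with the chemokine receptor Cxcr4 at -0.34 (adjusted p = 0.858). Of 35 light zone genes the cyclin Ccnd2 rose 1.67-fold and none fell, a call lost without DAF-TM library 1 (0.594) and without control libraries 1 (0.149) and 3 (0.0619). Adjusted over the list alone 1 rose and 2 fell (median -0.01, and 0.06 with upper-quartile factors; camera adjusted p = 0.416). The surface molecules Cd83 at -0.31 and Cd86 at -0.52, and Myc at 0.26, did not pass (adjusted p = 0.888, 0.261 and 0.945). Over the libraries left out, Cd83 ran from -0.38 to -0.15, Cd86 from -0.65 to -0.26 and Myc from 0.08 to 0.41. The 29 NF-kB and CD40 response genes (median 0.02, and -0.01 with RLE size factors; mean 0.04; set test direction down, camera adjusted p = 0.478), the 30 immediate early genes (0.13; 0.0951) and the 14 heat shock genes (0.11; 0.0597) neither passed nor had a called member. Against random lists of matched level, however, the last 2 lay at percentiles 99.6 and 99.98, at 100 each in DAF-TM library 1 and at 73.1 and 99.9 in library 2. Light zone and NF-kB and CD40 response genes lay at 99.0 and 98.9, but at 11.6 and 1.38 in library 2. Some medians near 0 joined opposite signs in DAF-TM libraries 1 and 2, 0.16 and -0.20 for light zone genes and 0.17 and -0.23 for NF-kB and CD40 response genes.

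Proliferation and metabolism lists shifted down by small amounts, again with no called member. With the loess correction for expression level, cholesterol synthesis alone among the lists of this paragraph kept its call (camera adjusted p = 3.83e-06). The others stood between 0.0792 and 0.774. The medians were -0.14 for 47 mitosis genes (camera adjusted p = 1.39e-05; adjusted p = 0.548 with an estimated correlation), -0.12 for 43 DNA replication genes (5.56e-05; 0.526), -0.17 for 28 repair and hypermutation genes (8.26e-05; 0.526), -0.17 for 65 oxidative phosphorylation genes (2.04e-09; 0.526) and -0.13 for 77 ribosomal protein genes (1e-06; 0.564). They were -0.09 for 40 MYC target and ribosome biogenesis genes (0.00688; 0.564), -0.07 for 49 mTORC1 targets (0.00159; 0.537), which stood at 0.00 with upper-quartile factors, -0.07 for 23 glycolysis genes (0.011; 0.466), which stood at 0.01 with those factors, -0.13 for 13 antigen presentation genes of MHC class II (0.0102; 0.548) and -0.14 for 30 apoptosis genes (0.0122; 0.478). Adjusted over the list alone 2 mTORC1 targets fell, 1 apoptosis gene rose and no member of the other 8 lists was called. Mki67, the marker of cycling cells, stood at 877 ± 95.5 and 850 ± 130.5 CPM (log2 -0.05, adjusted p = 0.985). Genes of cholesterol synthesis moved furthest: none of 24 passed over all genes, but 8 fell adjusted over the list alone (median -0.22; camera adjusted p = 5.11e-09; adjusted p = 0.334 with an estimated correlation), led by Insig1 (-0.60, adjusted p = 0.0882), Stard4 (-0.57, 0.162) and Sc5d (-0.55, 0.187). Leaving out 1 library moved Insig1 between -0.83 and -0.38, Stard4 between -0.72 and -0.44 and Sc5d between -0.70 and -0.30. The oxidative phosphorylation genes of lowest p were Atp5l (-0.42), Ndufb2 (-0.29) and Sdhb (-0.28), none passing.

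In DAF-TM library 2, fold changes also varied with expression level. There, genes above 100 CPM had a median of -0.23 against the controls and genes of 3 to 10 one of 0.39, while DAF-TM library 1 gave -0.04 and 0.02. Without DAF-TM library 2, no call remained for germinal centre identity (camera adjusted p = 0.0602), dark zone (0.17), mitosis (0.507), DNA replication (0.651), repair (0.449), glycolysis (0.3), antigen presentation (0.449), apoptosis (0.746) or cholesterol synthesis (0.0867), and MYC targets and mTORC1 targets turned upward (0.746 each). Without control library 2, MYC targets (0.121), antigen presentation (0.23) and apoptosis (0.131) did not pass, nor did glycolysis without control library 1 (0.124). Against 10000 random lists of matched level, the medians of germinal centre identity, mitosis, MYC targets and mTORC1 targets lay at percentiles 52.4, 38.3, 69.6 and 81.2. Those of oxidative phosphorylation, apoptosis, repair and ribosomal protein genes lay at percentiles 0.71, 0.98, 2.43 and 10.9. In DAF-TM library 1 alone, oxidative phosphorylation genes stood at -0.15 against -0.03 for random lists and ribosomal protein genes at -0.17 against -0.02, and both lists kept their calls without DAF-TM library 2 (9.22e-05 and 4.38e-06). In DAF-TM library 2 neither lay below its random lists, at -0.18 against -0.21 and -0.09 against -0.19. With the loess correction for level neither list passed (camera adjusted p = 0.0792 and 0.309), nor did germinal centre identity or dark zone (0.689 each). Cholesterol synthesis lay at percentile 0, and the interferon, FOXO1, T cell, macrophage and natural killer lists lay at percentile 100 in the fit of both libraries. Members of a list vary together (estimated correlation 0.378 for cholesterol synthesis and 0.154 for interferon genes), unlike the random genes. Percentiles can therefore be extreme through the variation of a single library. Ribosomal protein genes lay at percentile 0 in DAF-TM library 1 and at 100 in library 2.

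**Figure D3:**
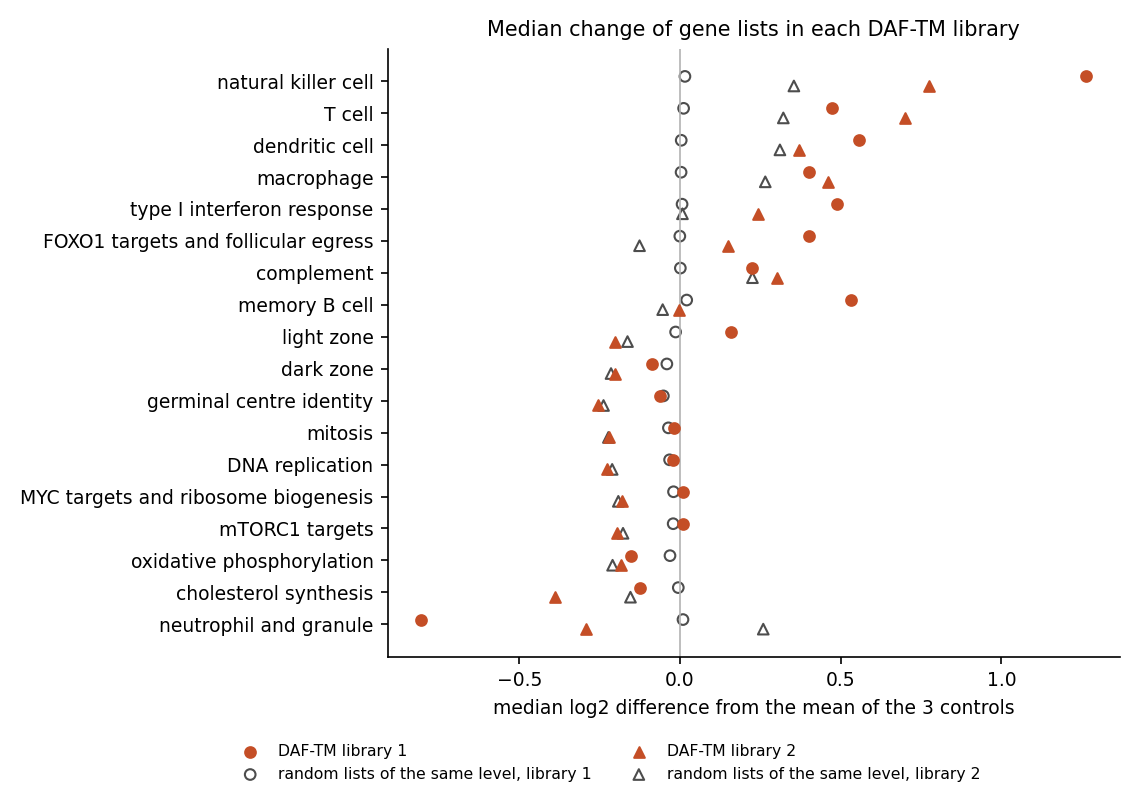
Filled symbols give the median log2 difference of each gene list from the mean of the 3 controls in DAF-TM library 1 (circle) and 2 (triangle), and open symbols the median of 10000 random lists of matched expression level in the same library. Natural killer genes, 7 of 22 chosen after their values were seen, lie at 1.26 and 0.78, while germinal centre identity lies at -0.06 and -0.26 beside its random lists at -0.05 and -0.24.

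Apart from Chi3l3 and Gm14308, the genes that fell did so by less than a factor of 2. They were Serpinf1, a secreted serpin (0.552 of the control level, adjusted p = 0.023), Gt(ROSA)26Sor (0.614, 0.0181), Cdv3 (0.632, 0.0277), the linker histone H1f0 (0.632, 0.0322) and the cold-inducible Rbm3 (0.642, 0.0426). Gt(ROSA)26Sor is the transcript of the locus that holds the cassette, and it stood at 67.6 ± 18.8 CPM in control and 41.6 ± 3.48 in DAF-TM cells. Of its neighbours, Thumpd3 at -0.25 and Setd5 at 0.33 on the log2 scale did not pass (adjusted p = 0.945 and 0.86), and no other of the 37 genes tested at and around the locus was called, or adjusted over the list alone. The median of the 37 was -0.15 against -0.03 for random lists of matched level (percentile 0.03; 1.39 in DAF-TM library 1 and 18.6 in library 2). Each of these 5 falls lost its call without DAF-TM library 1, with adjusted p of 0.537, 0.518, 0.558, 0.481 and 0.272 in the order named. The log2 values there were -0.55, -0.63, -0.39, -0.72 and -0.83, against -0.86, -0.70, -0.66, -0.66 and -0.64 with all libraries. Without control library 1, Serpinf1 (0.39), Gt(ROSA)26Sor (0.125), Cdv3 (0.283) and Rbm3 (0.302) were lost. Without control library 2, Gt(ROSA)26Sor (0.362), H1f0 (0.445) and Rbm3 (0.4) were lost, and without control library 3, Serpinf1 (0.0786), Cdv3 (0.0956) and H1f0 (0.326). Without DAF-TM library 2, Gt(ROSA)26Sor (0.137), H1f0 (0.535) and Rbm3 (0.886) were lost. DESeq2 called none of the falls. The seventh gene called lower, the predicted gene Gm14308, had 20, 12 and 3 counts in the controls and 0 in both DAF-TM libraries, which allows up to 3 counts in each, and no fold is given. Its call was lost without DAF-TM library 1 (0.384) and without DAF-TM library 2 (0.162), and it was not tested without control library 1 or 2.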

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

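The 6-column fit, the Xist covariate, the loess correction and the lists without Cd55 were chosen after the data were seen. Cd55 was called under all 16 alternatives, with log2 fold changes of 4.52 to 4.79 and a highest adjusted p of 6.70e-08. The counts of genes were less stable than the fold changes. Against 77 (70 higher, 7 lower), upper-quartile factors gave 39 (39 and 0), DESeq2 32 (32 and 0), with 5459 adjusted p left as NA, limma-voom 49 (2 lower), glmTreat 42, the 6 columns as deposited 11 (11 and 0) and the loess correction 25 (25 and 0). RLE factors and no filter each gave 11 lower. With Xist as a covariate 81 were called, 61 of them among the 77. The median prior degrees of freedom of the edgeR fit, which set how strongly the spread of a gene is drawn to that of others, fell from 1153 to 26.4, 7.34 and 19.5 with upper-quartile factors, 6 columns and loess; for Gzma the log2 fold change went from 1.98 to 1.87 with loess while the adjusted p rose from 1.72e-07 to 0.361. A set of 22 genes was called with TMM, upper-quartile factors, DESeq2, limma-voom and loess alike, among them Cd55, Ctse, Ccr7, Klf2, S1pr1, Plac8, Itgb7, Ly6d, Cnn3, Pml, Ifi203, Mndal, Siglech, Tyrobp, Vcam1, Ccl5, Nkg7, Ms4a4b, BC094916 and G530011O06Rik. All of these fits use the same 5 libraries, so their agreement is not independent support. Most of the 22 did not keep their call in every fit that left out 1 library. Leaving out 1 library gave 14 (without DAF-TM library 1) to 118 genes (without DAF-TM library 2), 12 to 107 of them higher and 2 to 16 lower.

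With the replicate number as a block, which the shared DAF-TM column permits as number 2 or as number 3, 61 genes (45 higher, 16 lower) or 105 (79 and 26) were called, and Cd55b reached -0.21 in the second of these. The deviations of DAF-TM library 1 correlated with those of control library 2 (0.254), not of control library 1 (-0.128).

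Of the 31 lists tested, 23 passed; 14 passed with loess (11 of the 23 and 3 others), 0 with an estimated correlation and 1 with fry. With Cd55 left out of the lists 23 passed, 0 with an estimated correlation and 0 with fry. Lists that turned direction were MYC targets (adjusted p = 0.746 without DAF-TM library 2, 0.689 with loess; 1.28e-05 to 0.746 over the libraries left out), mTORC1 targets (0.746 without DAF-TM library 2; 1.34e-06 to 0.746), antigen presentation (0.559 with loess), and, without DAF-TM library 1, marginal zone (0.843; 6.40e-16 to 0.843), memory (0.239; 1.16e-13 to 0.239) and neutrophil genes (0.568; 2.96e-12 to 0.568). Of the named genes the direction turned in Mki67 (0.021 with upper-quartile factors, 0.12 with loess, 0.026 without control library 1; -0.22 to 0.10 over the libraries left out), Cd55b (-0.42 without DAF-TM library 2, -0.13 without control library 2, -0.18 with the Xist covariate; -0.42 to 0.78), C3ar1 (-0.023 without DAF-TM library 2, -0.031 with the covariate, -0.013 with loess; -0.023 to 0.35), Cd46 (0.030 without control library 1, 0.018 without DAF-TM library 1; -0.30 to 0.030) and Cr2 (0.12 without DAF-TM library 2; -0.60 to 0.12), none of them called; the cause was not tested. Removing antibody genes was not run, because no row held one. With 2 DAF-TM libraries the depth and number of samples leave most changes below 2-fold undetected, as the simulation shows.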

Other observations

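The tests of natural killer markers not yet seen and of naive B cell members not yet seen, and the count of other splits, were written before their results were known; the other tests in this part were chosen after the result was seen. A test of sex written beforehand is left out, since it ran on called genes, and a call needs controls that agree.

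Several genes that rose belong to no list above. The interferon-inducible Pml rose 3-fold, from 18.3 ± 1.9 to 55 ± 25 CPM (edgeR adjusted p = 2.4e-13), Irgm1 rose 1.81-fold and the nucleic acid receptor Tlr7 rose 2.82-fold. Ly6d, a surface protein of B lineage cells, rose from 114 ± 24 to 238 ± 69 CPM (adjusted p = 4.07e-07). The adaptor Tyrobp rose 2.49-fold, the actin-binding Cnn3 2.56-fold and the selectin ligand Selplg 1.75-fold. The transcription factor Klf3 rose 2.57-fold. The protease Dpp4 rose 1.85-fold. Among these genes, Cnn3 alone kept its call without DAF-TM library 1 (adjusted p = 0.0162), the others lying between 0.0652 for Pml (log2 1.02 in place of 1.59) and 0.682 for Irgm1 (0.26 in place of 0.86); Selplg (0.132), Dpp4 (0.123) and Tlr7 (0.113) were also lost without control library 1, Tlr7 (0.0861) without control library 2 and Irgm1 (0.172) without control library 3.

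Among the markers of other cells that were higher in the DAF-TM libraries were 15 natural killer cell markers written down before their values were seen. Their median log2 fold change was 0.921 (95% bootstrap interval 0.645 to 1.01, drawn over genes, not libraries), and all 15 were positive. Random lists of matched level had a median of 0.21. In DAF-TM library 2 the markers stood at 0.59 against 0.36 for random lists (percentile 97.0), and in library 1 at 1.08 against 0.00 (percentile 100). These values go with more RNA of natural killer cells in these libraries, cells that the gate on B220, GL7 and Fas is meant to remove. Of the 22 markers 0 stand in another list and 2 reach 10 CPM in the controls; the most abundant, Il2rb, went from 14.8 ± 0.69 to 25.9 ± 8.3 and Gzma from 4.72 ± 2.66 to 18.3 ± 8.11. The tables argue against a higher background in DAF-TM library 1, which had the most natural killer RNA and the lowest receptor total, 585 CPM. They cannot decide on a lower share of germinal centre cells that raises all other types alike. The neutrophil median had an upper bound of 0.261, but that interval was drawn over genes, not libraries. The neutrophil list also turned without DAF-TM library 1. Nor can they decide on sex as the whole cause. With Xist as a covariate, the median of 78 T cell, macrophage, dendritic and natural killer (not seen) markers was 0.652 (0.588 to 0.795). It was 0.661 in the main fit. That interval too was drawn over genes, and among the controls only library 1 held Xist at a female level. Background in DAF-TM library 2 cannot be told, since the 78 markers had a median of 0.560 (0.421 to 0.690) there and silent receptor genes 0.452 (0.375 to 0.495), nor can more naive B cells: 12 members not seen before had a median of -0.0723 (-0.201 to 0.0649), but the bound set beforehand was wrong, since all 12 reach 10 CPM in the controls (median 254), which would hide a small share, and the 5 left out were all called. A lower share of germinal centre cells, sex, a biological difference between the genotypes and a difference in sorting stay open.

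In DAF-TM library 2, genes of low level were higher and abundant genes lower. Receptor genes silent in B cells had a median difference from the controls of 0.452 (0.375 to 0.495) in it, over the 332 that passed the count filter. This was close to 0.394 for genes at 1 to 10 CPM. A higher background of reads in that library would give such values. So would any other shift with level, since the receptor genes are themselves of low level, and the values do not tell these apart. DAF-TM library 1 did not share this trend: low and abundant genes differed there by 0.0447 (0.0319 to 0.0585, drawn over genes), against 0.619 in library 2. That speaks against genotype as the source, but it sets 1 library against 1. Whether library 1 held control RNA cannot be told either.

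DAF-TM library 1 held both Xist and Y-linked reads. Xist, at 291 CPM, lay between the male and the female libraries, as did the Y-linked total of 284, which is consistent with RNA of male and female mice in 1 library. Whether part of it came from a male control library cannot be told apart from pooling of mice: the genes called higher rose 2.20 times as far in library 1 as in library 2 (1.86 to 2.66), but the level of an unmixed library is unknown. Cd55 stood at 701 unadjusted CPM in library 1 and 803 in library 2; were a male control the source of all Y-linked reads, a share of 0.435 to 0.589, the rest would have held 1218 to 1672 CPM of Cd55, 1.52 to 2.08 times library 2. Of the 69 genes called higher besides Cd55, 64 were higher in library 1 than in library 2.

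The 10 splits of the 5 libraries into 3 and 2 are too few for a share under 0.05; the real split called 77 genes, 1 of 10 with as many, and the highest of the others 23.

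Within 20 Mb of the Rosa26 locus lay 5 of 75 called genes with a position, Gt(ROSA)26Sor itself left out, against 1.61% of those tested (Fisher's exact test, two-sided p = 0.00717), 4 of them killer cell lectin genes; without natural killer genes it was 1 of 65 (p = 1.0). On chromosome 1, which holds Cd55, lay 6 of 75 without Cd55 (Fisher's exact test, p = 0.457). The added list of 9 plasmacytoid dendritic cell genes had a median of 0.63 (-0.109 to 0.846), with no member called and 1 adjusted over the list alone.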
